A study of Homo sapiens with 32 samples.

How the data were processed

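The series measured messenger RNA in 8 established human cancer cell lines cultured for 24 h in 1 of 2 microdevices. Per the labels' protocols, 60000 cells were seeded in a device coated with poly-D-lysine, left to attach for 2 h and then cultured on with added medium. A549, PC3, MCF7, T47D and SKOV3 had been maintained in DMEM (5 lines) and PC9, LNCaP and OAW42 in RPMI (3 lines). RNA was extracted (RNeasy Plus Micro kit) and poly(A) libraries made (NEBNext Ultra II kit), per the labels' protocols. Whether these capture replication-dependent histones was not tested, so that list is uncertain. Each line had 2 libraries from the oxygen-limiting μMeRe device and 2 from the normoxic device, which gave 32 libraries in 16 groups. The labels do not say whether the 2 libraries of a group were separate cultures.

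Per the submitters' processing notes, the reads were processed with STAR and Partek against hg38, with no versions given. The deposited value of each gene is a normalised expression signal, made by the authors from reads assigned to genes, on a scale near CPM. The values of a library summed to 951755 to 1054420 (median 1000560), no gene was listed at 0, and the gene set (14887 to 15630 genes, median 15150) and the scaling were set separately for each line. Levels of different lines thus come from tables normalised separately, and tests between lines used fold changes within lines. The lowest value of a library lay between 0.0350 and 0.0739. At a tolerance of 0.1, 73.8% to 84.7% of the low values were whole multiples of it, so whole reads were not recovered and no count-based test was run. If the lowest value stands for 1 read, the total divided by it gives a depth of 13.9 to 28.8 M reads per library (median 19.9 M). The 10 highest genes took 5.80% to 9.61% of a library's total and mitochondrially encoded genes 1.59% to 5.52%. Nothing in the sources used here says whether the counting used strand, so genes that overlap, read through, lie antisense to or nearly copy another gene are uncertain. Coordinates are those of hg38 in the deposited annotation, counted from 1.

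All tests used log2(value + 1), so fold changes are on that scale and understate the change of low genes. A gene was tested in a line if its value was at least 1 in at least 2 of the 4 libraries. In each line, limma 3.58.1 in R 4.3.3 fitted the 4 libraries of that line with an intensity trend in the prior variance and no block, and Benjamini-Hochberg adjusted p under 0.05 counted as changed. The common response was limma on the 8 per-line log2 fold changes against 0, so that the line was the replicate. Genes whose response differed among lines were found with limma's moderated F-test of 7 contrasts between the lines' fold changes over all 32 libraries, and the lines of each organ were compared with interaction contrasts from the same model. Organ similarity was the mean correlation of fold changes, across genes, between lines of 1 organ minus that between the other pairs of lines, with an exact two-sided permutation test over the 105 ways of pairing 8 lines. Relations between list medians across the 8 lines used Pearson's r and Spearman's rho with exact permutation tests.

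The choice of tests, gene lists and named genes was made before the data were examined. It fixed 40 gene lists with 648 genes, of which 638 were found in the files. They covered hypoxia-inducible factor (HIF) targets, glycolysis, the pentose phosphate pathway, glycogen, the TCA cycle, nuclear and mitochondrially encoded respiratory chain subunits, sterol synthesis, fatty acid synthesis and oxidation, serine and one-carbon metabolism, glutamine and amino acid transport, ATF4 targets, endoplasmic reticulum chaperones, heat shock proteins, NRF2 targets, metallothioneins, S phase, G2/M, ribosomal proteins, ribosome biogenesis, p53 targets, collagen processing, mesenchymal and epithelial genes, NF-κB targets, interferon-stimulated genes, immediate early genes, secreted angiogenic factors, autophagy, androgen and oestrogen receptor targets, replication-dependent histones, identity genes of the 4 organs, and markers of fibroblasts, endothelium and leukocytes. A list with at least 3 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. Within a line the second test rests on the few residual degrees of freedom of 4 libraries, so over 280 tests it could hardly pass. A miss there does not decide whether a list changed. Adjustment ran over all lists and lines together, and separately over the lists of the common response and of the organ contrasts.

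The rule for naming genes took, for the common response, the 12 largest rises and 8 largest falls among genes that passed with the same sign in 8 lines. For each line it took the 3 largest rises and 3 largest falls that passed, with both μMeRe libraries on the same side of both normoxic libraries and a mean of at least 3 on the log2 scale. For the differences among lines it took the 6 genes with the largest SD of fold change, and for each organ 2 genes of each sign. Up to 4 members of each list per comparison could be named as examples, and SLC2A1, CA9, VEGFA, PDK1, LDHA, HIF1A and EPAS1 were always followed.

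The fits were tested on simulated data with 200 genes per comparison changed by known amounts. Of the genes changed 2-fold, the test within a line recovered 95.5% in A549, 85.1% in PC9, 82.1% in LNCaP, 86.6% in PC3, 59.7% in MCF7, 50.7% in T47D, 83.6% in OAW42 and 0% in SKOV3. SKOV3 recovered 75.8% at 4-fold, and the common test 100% at 2-fold. The F-test among lines recovered 17.9% at 2-fold and 95.5% at 4-fold. With hypoxia genes raised, camera called that list in 80 of 80 runs. Lists that share its genes were called in 245 of 400 tests and other lists in 16 of 2320. These runs do not give the false-call rate of real lists, whose genes may vary together.

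The alternatives chosen with the tests were a pseudocount of 0.1, no filter on low values, median-of-ratios rescaling, a replicate block, libraries as replicates, lines of 1 medium, each library or line left out, and a spread shared over all 32 libraries. Added after the data were seen were the removal of a transcript length and GC trend (splines with 5 degrees of freedom), crossed replicate numbers, the estimated correlation, the common response without SKOV3 and T47D, list medians with 1 library left out, and lists without the members they share with the hypoxia list. Other computations and plots used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genes that entered no list and no rule, and the reads themselves, were not analysed here beyond the counts given.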

Results

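Messenger RNA was profiled in 8 human cancer cell lines, 2 from each of 4 organs: A549 and PC9 from lung, LNCaP and PC3 from prostate, MCF7 and T47D from breast, and OAW42 and SKOV3 from ovary. Each line spent 24 h in a μMeRe device or in a normoxic device of equal dimensions. In the μMeRe device a circular patterned monolayer lies between a polycarbonate top and a glass bottom, so that the cells' own consumption lowers oxygen faster than it can diffuse in from the side. The normoxic device lacks the polycarbonate barrier. Each of the 16 combinations of line and device had 2 libraries, with a signal for 14887 to 15630 genes and an inferred depth of 13.9 to 28.8 M reads. Replicate libraries of 1 line and device correlated across genes at Pearson's r of 0.955 (SKOV3, normoxic) to 0.993 (PC9, normoxic). As replicates may not be separate cultures, p-values measure the spread between these samples, which may be technical.

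The first comparison asked which genes responded to the μMeRe device in the same way across the lines. Genes of the hypoxia response, glycolysis and angiogenic signalling rose, by up to 8.83-fold on average for NDRG1, a stress gene induced by hypoxia-inducible factor (HIF). All 24 measured HIF targets and 17 of 18 glycolysis genes rose. Falls were smaller, and no gene fell 2-fold: the largest was that of PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, at log2 −0.69 ± 0.09 (SE, n = 8 lines, limma adjusted p = 0.00026). Some genes of sterol synthesis (8 of 22), heat shock proteins (6 of 11) and the TCA cycle (6 of 17) were among those that fell, although their lists did not pass camera with an estimated correlation (adjusted p = 0.37, 0.448 and 0.37).

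NDRG1 (hg38 chromosome 8, 133237175 to 133302022, minus strand) rose by log2 3.14 ± 0.29 (SE, n = 8 lines, limma adjusted p = 2.4e-05). In T47D its signal went from 2.67 ± 0.0221 in the normoxic device to 194 ± 10.1 in the μMeRe device (SD, n = 2), and in SKOV3 from 291 ± 22.1 to 1066 ± 137. ANGPTL4 (chromosome 19, 8363289 to 8374370, plus strand), a secreted inhibitor of lipoprotein lipase, rose by 2.98 ± 0.30. ALDOC (chromosome 17, 28573115 to 28576948, minus strand), a glycolytic aldolase, rose by 2.64 ± 0.18, and LOX (chromosome 5, 122063195 to 122078413, minus strand), which crosslinks collagen, by 2.45 ± 0.23. PFKFB4, a regulator of glycolytic flux (2.00 ± 0.21), ENO2, a glycolytic enolase (1.95 ± 0.16), HILPDA, a lipid droplet protein (1.94 ± 0.22), and HK2, the hexokinase that traps glucose (1.90 ± 0.18), followed. BNIP3, a mitophagy receptor, rose by 1.86 ± 0.15, DHRS3, a retinal reductase, by 1.69 ± 0.24, P4HA1, a collagen prolyl hydroxylase, by 1.60 ± 0.13, and DDIT4, an inhibitor of mTORC1, by 1.60 ± 0.17. The other large falls were those of HELLS, a chromatin remodeller (−0.68 ± 0.17), ESCO2, a cohesin acetyltransferase (−0.68 ± 0.17), SLC2A6, a hexose transporter (−0.67 ± 0.08), KITLG, the ligand of the receptor KIT (−0.66 ± 0.09), PIGW, an enzyme of GPI anchor synthesis (−0.65 ± 0.11), MARS2, the mitochondrial methionyl-tRNA synthetase (−0.63 ± 0.11), and CDC25A, a cell cycle phosphatase (−0.62 ± 0.15). These 20 genes were picked from those with the same sign in 8 lines.

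Over all genes tested in the 8 lines, 1938 of 10963 changed, 967 up and 971 down (limma, adjusted p under 0.05). Of these, 47 rose at least 2-fold and 0 fell at least 2-fold, and 3734 genes had an unadjusted p under 0.05. Of the 1938, 1079 had the same sign in 8 lines. The count was 1264 without LNCaP and 1223 without PC3. Without SKOV3 and T47D, whose μMeRe replicates differed most (SD of the difference 0.463 and 0.445), it was 963, of which 915 were among the 1938, and ESCO2 at −0.42 no longer passed.

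**Figure D1:**
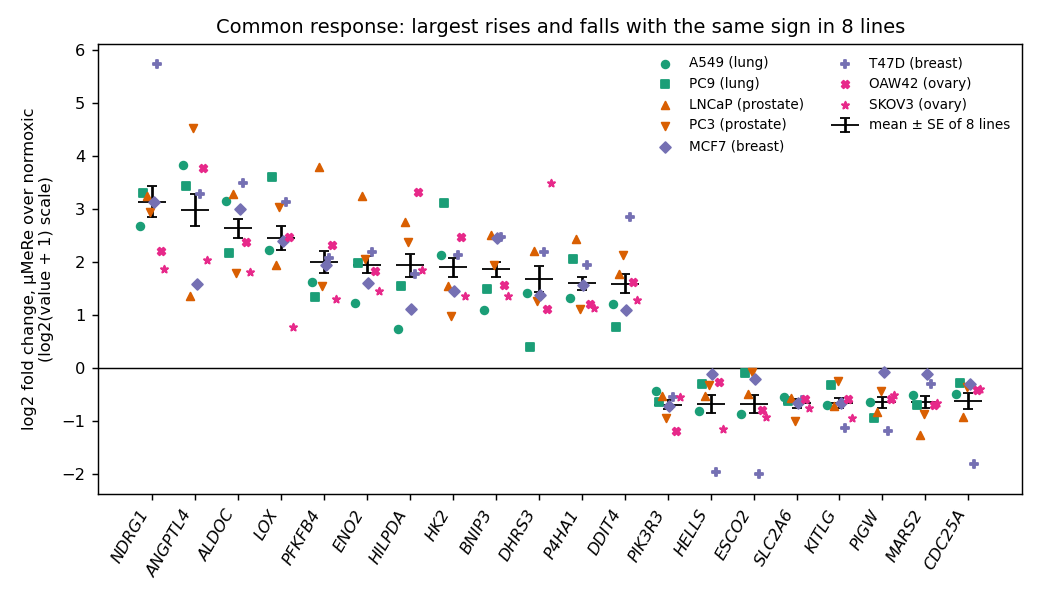
The log2 fold change of μMeRe over normoxic devices (y axis) of the 12 largest rises and 8 largest falls of the common response (x axis). Each symbol is 1 line, coloured by organ, and bars give the mean and SE of 8 lines; NDRG1 reached 5.73 in T47D, and ESCO2 was lowest in T47D at −2.0.

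The HIF pathway's textbook targets rose together: SLC2A1, the main glucose transporter, by 1.24 ± 0.13 (SE, n = 8 lines), VEGFA, the angiogenic growth factor, by 1.53 ± 0.23, PDK1, which diverts pyruvate from the TCA cycle, by 1.22 ± 0.16, and LDHA, lactate dehydrogenase, by 1.09 ± 0.13 (limma adjusted p = 5.1e-05, 0.0012, 0.00042 and 0.00016). EPAS1, which encodes HIF-2α, rose by 0.62 ± 0.12 (adjusted p = 0.0041). HIF1A, which encodes HIF-1α, a subunit regulated mainly by protein turnover, had a mean of −0.27 ± 0.11 and did not pass (limma adjusted p = 0.089, negative in 5 of 8 lines), although it passed at −0.36 without MCF7. Within lines HIF1A fell in A549 (−0.53 ± 0.08), PC9 (−0.63 ± 0.07), PC3 (−0.66 ± 0.06) and OAW42 (−0.40 ± 0.10). In OAW42 it no longer passed without μMeRe library 2 (−0.37) or normoxic library 1 (−0.31). CA9, a HIF-induced carbonic anhydrase, was below the filter in OAW42 and so had no common value.

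By group, 24 of 24 HIF targets rose (24 adjusted over the list alone, median 1.23), as did 17 of 18 glycolysis genes (17 adjusted over the list alone, median 1.02), among them ALDOA at 1.32 ± 0.13, and 5 of 5 secreted angiogenic factors (5 adjusted over the list alone, median 0.77), among them VEGFB at 0.51 ± 0.12. Camera gave adjusted p = 8.72e-28, 3.63e-21 and 2.27e-05, and these 3 lists also passed with an estimated correlation (adjusted p = 0.0316 for each), as no other list did. Without the members they share with the hypoxia list, the glycolysis list had adjusted p = 0.0474 and the angiogenic list adjusted p = 0.108 with an estimated correlation. Of 9 collagen genes 5 rose (8 adjusted over the list alone), for example P4HA2 at 1.20 ± 0.16, as did 2 of 3 mesenchymal genes (3 alone), for example VIM at 0.69 ± 0.13, and 5 of 7 immediate early genes (5 alone), for example JUN at 0.77 ± 0.16. Their lists passed at adjusted p = 4.03e-07, 0.00592 and 0.000276, but had adjusted p = 0.0902 with an estimated correlation. Of 9 glycogen genes 5 rose (6 rose and 2 fell adjusted over the list alone), with the branching enzyme GBE1 at 0.97 ± 0.11 and the phosphorylase PYGL at 0.87 ± 0.13, and 3 of 4 NF-κB targets rose (3 alone), with RELB at 0.71 ± 0.12. At the preset correlation camera gave adjusted p = 0.00207 and 0.00634, or adjusted p = 0.133 and 0.157 with an estimated correlation. Ribosomal protein genes rose by small amounts, 34 of 56 (48 alone, median 0.19), for example RPL12 at 0.35 ± 0.07. ATF4 targets rose in 6 of 14 cases (7 alone, median 0.33), for example VLDLR at 1.16 ± 0.19, and epithelial genes in 4 of 10 (4 rose and 1 fell alone), for example KRT19 at 0.69 ± 0.14. These 3 lists passed at adjusted p = 1.8e-16, 0.00207 and 0.0234, and had adjusted p = 0.36, 0.37 and 0.233 with an estimated correlation.

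Among the groups that fell, sterol synthesis had 8 of 22 genes lower and none higher (8 adjusted over the list alone, median −0.18), with ACAT2, a thiolase of sterol synthesis, at −0.55 ± 0.08 and DHCR24 at −0.45 ± 0.09. Fatty acid synthesis had 2 of 10 lower (4 alone), with the elongase ELOVL6 at −0.54 ± 0.09, and the TCA cycle 6 of 17 lower (1 rose and 7 fell alone), with IDH3A at −0.30 ± 0.06 and FH at −0.26 ± 0.06. From camera came adjusted p = 0.00033, 0.0137 and 0.0178, and adjusted p = 0.37, 0.554 and 0.37 with an estimated correlation. Heat shock genes fell in 6 of 11 cases and rose in 1 (the same counts alone), with the co-chaperone DNAJA1 at −0.45 ± 0.08, ribosome biogenesis genes fell in 7 of 22 and rose in 2 (the same alone), with NOP56 at −0.42 ± 0.10, and S phase genes fell in 4 of 25 and rose in 1 (11 fell and 1 rose alone), with PCNA at −0.53 ± 0.14. Nuclear respiratory chain genes fell in 8 of 74 (4 alone, median −0.07), with NDUFB6 at −0.33 ± 0.07. These 4 lists passed at adjusted p = 0.0178, 0.00854, 0.00151 and 0.0264, and had adjusted p = 0.448, 0.59, 0.671 and 0.812 with an estimated correlation.

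The remaining lists did not pass in the common test: medians were −0.13 for the pentose phosphate pathway, −0.05 for fatty acid oxidation, −0.05 for serine and one-carbon metabolism, −0.11 for endoplasmic reticulum chaperones, 0.08 for G2/M, 0.04 for p53 targets, 0.09 for autophagy, 0.17 for androgen receptor targets and 0.13 for oestrogen receptor targets (camera adjusted p = 0.688, 0.713, 0.843, 0.273, 0.228, 0.371, 0.143, 0.0852 and 0.426). For 5 further lists that did not pass, the median, the mean or the test differed in sign. Mitochondrially encoded respiratory chain genes had a median of −0.06 and a test direction of up, glutamine and amino acid genes a median of −0.01, a mean of 0.03 and a direction of down, and NRF2 targets a median of −0.03, a mean of 0.05 and a direction of down. Interferon-stimulated genes had a median of −0.07 and a mean of 0.02, and replication-dependent histones a median of −0.05 and a mean of 0.05, both with a direction of up (camera adjusted p = 0.97, 0.97, 0.97, 0.944 and 0.835 in that order). Of the metallothioneins, which buffer zinc and copper, MT1X rose by 1.75 ± 0.29 and MT2A by 1.03 ± 0.20 (SE, n = 8 lines), too few for a list test.

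**Figure D2:**
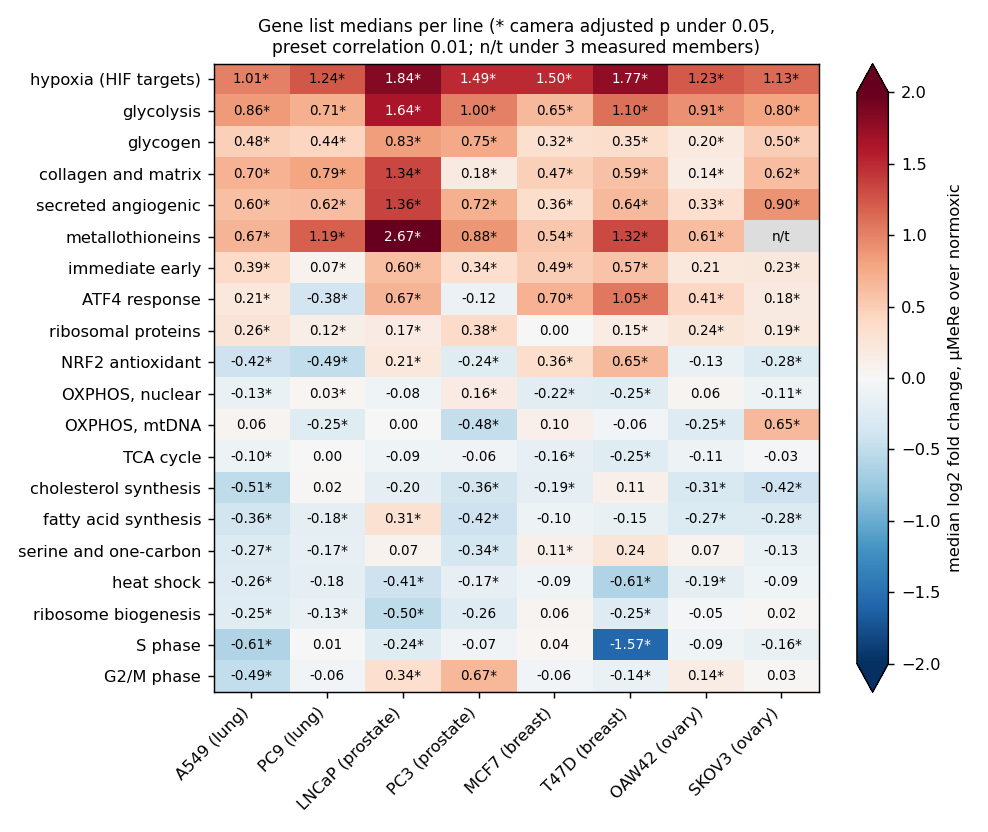
Median log2 fold change of μMeRe over normoxic devices (colour and printed value) for 20 gene lists (y axis) in each line (x axis), with an asterisk where camera passed at the preset correlation and n/t where a list had under 3 measured members. The hypoxia list was positive in all 8 lines, from 1.01 in A549 to 1.84 in LNCaP, while the S phase list reached −1.57 in T47D and the ATF4 list ran from −0.38 in PC9 to 1.05 in T47D (0.52 without μMeRe library 2).

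Comparisons within lines asked how each cancer type responded. In A549, a lung adenocarcinoma line, HIF targets and matrix genes rose while sterol synthesis, cell cycle and NRF2 target genes fell. CA9 (chromosome 9, 35673928 to 35681159, plus strand) rose from a signal of 2.54 ± 1.66 to 69.3 ± 21.9 (SD, n = 2), a log2 change of 4.36 ± 0.27 (limma adjusted p = 5.1e-08), ANGPTL4 rose by 3.83 ± 0.14 and ALDOC by 3.15 ± 0.18. HMGCS1, the synthase at the entry to sterol synthesis, fell from 106 ± 4.09 to 44.8 ± 3.69 (log2 −1.23 ± 0.10), and PCSK9, which degrades the LDL receptor, fell by 1.12 ± 0.11 on the log2 scale. SULT1A3, a sulfotransferase whose reads cannot be told from those of a near-identical copy, was at −1.21 ± 0.30, and at −0.92 and not passing without normoxic library 1. HIF targets rose in 27 of 31 cases (28 adjusted over the list alone) and glycolysis genes in 17 of 19 (17 alone), with HK2 at 2.13. The camera test gave adjusted p = 5.35e-33 and 9.28e-22, adjusted p = 0.331 for both with an estimated correlation. Sterol synthesis genes fell in 16 of 24 cases (18 alone), with INSIG1 at −0.92 and ACAT2 at −0.90, and fatty acid synthesis genes in 7 of 11 (8 alone), with ELOVL6 at −0.68. Tested by camera, this gave adjusted p = 3.26e-17 and 6.53e-06, adjusted p = 0.331 for both with an estimated correlation. S phase genes fell in 21 of 26 cases (24 fell and 1 rose alone), with the flap endonuclease FEN1 at −0.82 and CDC6 at −0.79, and G2/M genes in 21 of 26 (23 alone), with CDK1 at −0.72 and KIF11 at −0.70. The list test gave adjusted p = 1.69e-18 and 5.88e-16, or adjusted p = 0.399 and 0.41 with an estimated correlation. The G2/M median of −0.49 shrank to −0.32 without μMeRe library 1. NRF2 targets fell in 10 of 14 (11 alone), with the glutathione synthesis subunits GCLM at −0.73 and GCLC at −0.56, while collagen genes rose in 11 of 16 (13 alone), with LOXL2 at 1.81. In camera this gave adjusted p = 1.47e-10 and 1.61e-12, or adjusted p = 0.399 and 0.354 with an estimated correlation.

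In all, 2208 of 14430 genes changed in A549, 1351 up and 857 down. The count was 1013 without normoxic library 1 and 1059 without normoxic library 2, and 1019 rose and 1154 fell once a transcript length and GC trend was removed. Smaller movements included ribosomal protein genes, up in 28 of 56 cases (42 alone), with RPS9 at 0.57, mesenchymal genes, up in 5 of 12 (6 alone), with VIM at 1.51, and heat shock genes, down in 6 of 12 and up in 1 (7 and 1 alone), with HSPE1 at −0.76. Camera gave adjusted p = 1.1e-13, 0.00017 and 0.00122, or adjusted p = 0.331, 0.399 and 0.399 with an estimated correlation. The identity genes AGR2 and AKR1B10 had values of −0.39 and −0.64, and AGR2 did not pass without normoxic library 1 (−0.24). Lung identity, endothelial and leukocyte lists had under 3 measured members in each line and were not tested, and the 4 fibroblast markers measured in A549 did not pass (camera adjusted p = 0.639).

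PC9, an EGFR-mutant lung adenocarcinoma line, combined a hypoxia response with falls in genes of amino acid supply and the antioxidant response. LOX rose from a signal of 4.83 ± 0.871 to 69.3 ± 0.665 (SD, n = 2), a log2 change of 3.60 ± 0.15 (limma adjusted p = 2.2e-09). IGFBP3, a secreted binder of insulin-like growth factors, rose by 3.59 ± 0.14 and ANGPTL4 by 3.44 ± 0.30. ASNS (chromosome 7, 97851677 to 97872542, minus strand), which makes asparagine, fell from 81.0 ± 2.26 to 18.8 ± 3.81 (log2 −2.06 ± 0.13, adjusted p = 1.1e-07), TP53INP1, a p53-induced autophagy protein, was at −1.61 ± 0.26 and MAB21L4 at −1.60 ± 0.15. HIF targets rose in 30 of 32 cases (30 adjusted over the list alone), with NDRG1 at 3.31, and glycolysis genes in 17 of 19 (17 alone), with the glucose transporter SLC2A3 at 2.96. At the preset correlation camera gave adjusted p = 2.33e-46 and 7.27e-35, adjusted p = 0.331 for both with an estimated correlation. NRF2 targets fell in 13 of 14 cases (13 alone), with SRXN1 at −0.61, while HMOX1, haem oxygenase, rose by 0.97 (1 alone). Glutamine and amino acid transport genes fell in 7 of 13 cases (8 fell and 1 rose alone), with the cystine transporter SLC7A11 at −1.55, and mitochondrially encoded respiratory chain genes in 8 of 13 (9 alone), with MT-CO3 at −0.67. The camera test gave adjusted p = 9.9e-14, 2.55e-06 and 8.12e-08 for the 3 lists, adjusted p = 0.331 for each with an estimated correlation. ATF4 targets fell in 6 of 15 cases and rose in 2 (8 and 3 alone), with CHAC1, a glutathione-degrading enzyme, at −1.20 and CEBPG at −0.91. Tested by camera, this gave adjusted p = 0.0457, or adjusted p = 0.48 with an estimated correlation. Serine synthesis genes fell in 3 of 10 (5 fell and 1 rose alone), with PSAT1 at −1.59. The list test gave adjusted p = 0.0156, or adjusted p = 0.566 with an estimated correlation. The 3 measured metallothioneins rose (3 alone), with MT1X at 1.97, and collagen genes rose in 9 of 15 cases (12 alone), with P4HA1 at 2.06. In camera this gave adjusted p = 5.04e-06 and 1.19e-16, or adjusted p = 0.354 and 0.331 with an estimated correlation. Sterol synthesis, S phase and G2/M genes did not pass as lists, with medians of 0.02, 0.01 and −0.06 (camera adjusted p = 0.226, 0.639 and 0.155). In all, 1711 of 14358 genes changed, 893 up and 818 down. The count was 776 without normoxic library 1 and 753 without normoxic library 2, and 3387 and 2679 without μMeRe libraries 1 and 2.

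LNCaP, an androgen-responsive prostate line, had the highest glycolysis median of the 8 lines and raised ATF4 targets beside its hypoxia response. Its HIF target median was also the highest, but lay at 1.58 without μMeRe library 2, below that of T47D. PLOD2 (chromosome 3, 146069440 to 146163653, minus strand), a collagen lysyl hydroxylase, rose from a signal of 0.262 ± 0.111 to 39.8 ± 18.2 (SD, n = 2), a log2 change of 4.94 ± 0.28 (limma adjusted p = 1.8e-07). PLA2G4D, a phospholipase, rose by 4.08 ± 0.21 and PFKFB4 by 3.80 ± 0.16. TFRC, the transferrin receptor, fell from 449.5 ± 15.2 to 145 ± 4.38 (log2 −1.62 ± 0.13), FAM13B from 35.5 ± 2.70 to 9.74 ± 1.19 (−1.77 ± 0.18), and MAB21L4 was at −1.65 ± 0.24. HIF targets rose in 29 of 30 cases (30 adjusted over the list alone, median 1.84), with BHLHE40 at 3.16, and glycolysis genes in 17 of 18 (17 alone, median 1.64), with GPI at 2.41 and ALDOA at 2.32. Camera gave adjusted p = 4.96e-51 and 1.25e-29, adjusted p = 0.331 for both with an estimated correlation. ATF4 targets rose in 10 of 15 cases (11 alone), with VLDLR at 1.79 and DDIT3, the stress factor CHOP, at 1.54, and collagen genes in 9 of 11 (10 alone), with P4HA2 at 2.26 (median 1.34, or 0.67 without the 2 hypoxia members). At the preset correlation camera gave adjusted p = 1.41e-11 and 6.97e-13, adjusted p = 0.331 for both with an estimated correlation. p53 targets rose in 5 of 17 cases and fell in 1 (6 and 1 alone), with the stress cytokine GDF15 at 3.70 and BBC3 at 1.73, and the NRF2 list rose through 2 of 12 genes (2 alone), HMOX1 at 3.50 and OSGIN1 at 1.09. The camera test gave adjusted p = 0.000646 and 0.00564, or adjusted p = 0.348 and 0.399 with an estimated correlation. Fatty acid synthesis rose in 3 of 11 cases (4 alone, adjusted p = 0.000907, or adjusted p = 0.428 with an estimated correlation). Its members were SCD at 0.87, ACLY at 0.71 and FASN at 0.63. Ribosome biogenesis genes fell in 11 of 22 cases (14 alone), with NOP2 at −0.93, and heat shock genes in 5 of 11 (6 fell and 1 rose alone), with HSPH1 at −0.88. Tested by camera, this gave adjusted p = 8.4e-09 and 0.00179, or adjusted p = 0.399 and 0.428 with an estimated correlation. Endoplasmic reticulum chaperones fell in 3 of 18 cases (2 rose and 5 fell alone, median −0.31, adjusted p = 0.00988, or adjusted p = 0.396 with an estimated correlation). Without μMeRe library 2 the median of heat shock genes went from −0.41 to −0.24, that of NRF2 targets from 0.21 to 0.04 and that of p53 targets from 0.21 to 0.12. Androgen receptor targets rose in 4 of 12 cases and fell in 1 (6 and 3 alone), with TMPRSS2 at 0.95 and ACP3, prostatic acid phosphatase, at −1.09 (adjusted p = 0.0464, adjusted p = 0.399 with an estimated correlation, and adjusted p = 0.329 without NDRG1, which is also a HIF target, and not passing with the length and GC trend removed). Prostate identity genes rose in 2 of 6 cases (4 rose and 1 fell alone, adjusted p = 0.0463, or adjusted p = 0.399 with an estimated correlation). In all, 1235 of 14683 genes changed, 730 up and 505 down, or 1271 up and 1407 down with the length and GC trend removed. The count was 380 and 425 without normoxic libraries 1 and 2, and 4101 and 3064 without μMeRe libraries 1 and 2. Without normoxic library 1 SCD (0.85), ACLY (0.74) and FASN (0.54) did not pass, nor did ACLY (0.67) and FASN (0.71) without normoxic library 2.

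PC3, an androgen-independent prostate line, combined rises in ribosomal proteins and mitosis and falls in lipid synthesis with the hypoxia response. ANGPTL4 rose from a signal of 10.6 ± 0.370 to 268 ± 41.6 (SD, n = 2), a log2 change of 4.53 ± 0.10 (limma adjusted p = 8.3e-17), ADM, the vasodilator peptide adrenomedullin, by 3.62 ± 0.19 and IGFBP3 from 86.4 ± 1.74 to 842 ± 134 (3.26 ± 0.08). SSTR5-AS1, whose reads may belong to its antisense partner, was at −1.54 ± 0.11, SLC46A3, a lysosomal transporter, fell by 1.45 ± 0.24 on the log2 scale and CHAC1 by 1.19 ± 0.14. HIF targets rose in 30 of 31 cases (30 adjusted over the list alone), with ENO2 at 2.06, and glycolysis genes in 17 of 18 (17 alone), with PGK1 at 1.50. The list test gave adjusted p = 5.11e-44 and 5.14e-29, adjusted p = 0.331 for both with an estimated correlation. Ribosomal protein genes rose in 55 of 56 cases (55 alone, median 0.38), with RPL38 at 0.71, and G2/M genes in 22 of 26 (24 alone, median 0.67), with cyclin A2 (CCNA2) at 1.02 and TOP2A at 0.98. In camera this gave adjusted p = 6.49e-31 and 5.4e-16, or adjusted p = 0.331 and 0.404 with an estimated correlation. Sterol synthesis genes fell in 17 of 24 cases (19 alone), with IDI1 at −0.61, and fatty acid synthesis genes in 10 of 11 (10 alone), with the synthase FASN at −0.73 and ACACA at −0.61, while 1 rose. Camera gave adjusted p = 1.69e-08 and 5.35e-06, adjusted p = 0.331 for both with an estimated correlation. Amino acid transport genes fell in 8 of 13 cases (8 alone), with SLC7A11 at −0.89, and GPT2, a mitochondrial alanine transaminase, rose by 1.16. At the preset correlation camera gave adjusted p = 0.000646, or adjusted p = 0.331 with an estimated correlation. Nuclear respiratory chain genes rose in 29 of 75 cases and fell in 2 (32 and 2 alone), with NDUFA6 at 0.48, whereas mitochondrially encoded ones fell in 8 of 13 (8 alone), with MT-CYB at −0.83. The camera test gave adjusted p = 0.000108 and 6.65e-05, or adjusted p = 0.49 and 0.565 with an estimated correlation. Immediate early genes rose in 9 of 12 cases (9 alone), with DUSP1 at 1.06, and NF-κB targets in 4 of 10 (4 alone), with CXCL8, the neutrophil attractant, at 1.29. Tested by camera, this gave adjusted p = 1.5e-06 and 0.00584, or adjusted p = 0.331 and 0.506 with an estimated correlation. ATF4 targets rose in 3 and fell in 6 of 15 cases (3 and 6 alone) and did not pass as a list (median −0.12, camera adjusted p = 0.616). Of 4 fibroblast markers 2 fell (2 alone), PDGFRA at −0.69 and COL1A1 at −0.34 (not passing at −0.29 without normoxic library 2), and the list did not pass (camera adjusted p = 0.2). In all, 3958 of 14453 genes changed, 1999 up and 1959 down, or 2254 up and 1470 down after median-of-ratios rescaling, and 2358 changed without normoxic library 2. This was the highest count of the 8 lines when each kept its own spread, but with a spread shared over 32 libraries it was 612, against 1672 in T47D and 852 in LNCaP.

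MCF7, an oestrogen receptor positive breast line, raised HIF targets and some amino acid transport and ATF4 target genes. CASP14, a caspase of keratinocyte differentiation, rose from a signal of 0.635 ± 0.672 to 16.1 ± 5.65 (SD, n = 2), a log2 change of 3.41 ± 0.38 (limma adjusted p = 2.5e-06). NDRG1 rose by 3.14 ± 0.20 and ALDOC by 3.0 ± 0.28. The largest falls were those of HYPK, a chaperone subunit whose gene lies next to a readthrough partner (−1.60 ± 0.34), the acetyltransferase NAT1 (−1.59 ± 0.32) and ANKRD35 (−1.50 ± 0.34). None of the 3 passed in every leave-out: HYPK was at −1.32 without μMeRe library 2 and −1.21 without normoxic library 2, NAT1 at −1.45 without μMeRe library 2 and −1.29 without normoxic library 1, and ANKRD35 at −1.31, −1.35 and −1.65 without μMeRe library 2, normoxic library 1 and normoxic library 2. HYPK (−1.63) and ANKRD35 (−1.43) did not pass with a transcript length and GC trend removed either. Of 30 HIF targets 24 rose (29 adjusted over the list alone), with BHLHE40 at 2.50 and VEGFA at 1.64, and glycolysis genes in 6 of 18 (12 alone), with PGM1 at 1.85. The list test gave adjusted p = 2.57e-88 and 2.5e-23, adjusted p = 0.331 for both with an estimated correlation. Amino acid transport genes rose in 3 of 13 cases (4 alone), with SLC7A11 at 2.03 and SLC7A5 at 1.76, ATF4 targets in 4 of 14 (9 alone) and collagen genes in 4 of 13 (5 alone), with P4HA2 at 1.65. In camera this gave adjusted p = 5.39e-07, 2.76e-11 and 7.53e-10, adjusted p = 0.331 for each with an estimated correlation. Oestrogen receptor targets rose in 1 of 14 cases (4 alone), AREG, the growth factor amphiregulin, at 1.06 ± 0.20, which did not pass without μMeRe library 1 (1.15) or 2 (0.98), and their list passed. Camera gave adjusted p = 1.89e-07, or adjusted p = 0.331 with an estimated correlation. No nuclear respiratory chain gene changed alone, although the list of 75 lay lower (0 alone, median −0.22, or −0.02 without normoxic library 2, adjusted p = 9.26e-09, or adjusted p = 0.606 with an estimated correlation). S phase genes and breast identity genes did not pass as lists (medians 0.04 and −0.11, camera adjusted p = 0.385 and 0.639). In all, 95 of 14473 genes changed, 80 up and 15 down (limma; 1057 had an unadjusted p under 0.05). The count was 159 without μMeRe library 1 and 35 without μMeRe library 2.

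In T47D, another oestrogen receptor positive breast line, NDRG1 rose 53.1-fold on the log2(value + 1) scale and the S phase genes lay far lower in the μMeRe device. NDRG1 changed by log2 5.73 ± 0.16 (limma adjusted p = 0.00026), SCNN1G, a subunit of the epithelial sodium channel, rose from a signal of 1.34 ± 0.437 to 29.8 ± 5.62 (SD, n = 2), or 3.72 ± 0.25, and CA9 rose by 3.60 ± 0.33. Of 30 HIF targets 16 rose (26 adjusted over the list alone, median 1.77) and glycolysis genes in 9 of 18 (13 alone, median 1.10), with SLC2A1 at 1.72. At the preset correlation camera gave adjusted p = 1.95e-28 and 8.85e-13, adjusted p = 0.331 for both with an estimated correlation. SLC2A1 did not pass without normoxic library 1 (1.63) or 2 (1.79). None of 26 S phase genes passed over all genes, but 26 fell adjusted over the list alone, with a median of −1.57 (−0.98 without μMeRe library 2). The camera test gave adjusted p = 1.36e-15, or adjusted p = 0.446 with an estimated correlation. The signals of E2F1, the S phase transcription factor, were 39.5 and 12.2 in the μMeRe libraries against 90.8 and 93.6 in the normoxic ones, and those of MCM3, a subunit of the replicative helicase, were 95.2 and 23.8 against 204 and 204. The log2 change of MCM3 was −3.05 and −1.09 without μMeRe libraries 1 and 2. ATF4 targets rose in 1 of 15 cases (7 alone, median 1.05) and metallothioneins in 2 of 3 (2 alone), with MT1X at 3.56 ± 0.36. Tested by camera, this gave adjusted p = 0.00021 and 0.000904, or adjusted p = 0.506 and 0.332 with an estimated correlation. The ATF4 median was 0.52 without μMeRe library 2 and 1.60 without μMeRe library 1. Heat shock genes had 0 changes over all genes and 5 falls of 12 alone (median −0.61, or −0.30 without μMeRe library 2), and histone genes 1 rise of 10 (6 rises and 1 fall alone, median 0.60), with adjusted p = 0.000646 and 0.00222, or adjusted p = 0.428 and 0.399 with an estimated correlation. Serine and one-carbon genes did not pass and had a median of 0.24 and a mean of −0.21 (camera adjusted p = 0.693), and oestrogen receptor targets and breast identity genes did not pass either (medians −0.38 and −0.34, camera adjusted p = 0.0966 and 0.105). In all, 49 of 14439 genes rose and 0 fell (limma; 3220 had an unadjusted p under 0.05, 1574 of them higher). The counts were 338 up and 258 down with a replicate block, and with a spread shared over 32 libraries 850 rose and 822 fell. The μMeRe replicates differed with an SD of 0.445 on the log2 scale against 0.171 for the normoxic ones, and the count was 6086 and 2690 without μMeRe libraries 1 and 2 and 12 and 9 without normoxic libraries 1 and 2.

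OAW42, an ovarian carcinoma line, raised HIF and ATF4 targets and lowered sterol synthesis genes. DPYSL4, a dihydropyrimidinase-like protein, rose from a signal of 0.179 ± 0.0708 to 29.6 ± 13.9 (SD, n = 2), a log2 change of 4.62 ± 0.28 (limma adjusted p = 5.4e-08). SLC8A2, a sodium-calcium exchanger, rose by 4.03 ± 0.36 and ANGPTL4 by 3.77 ± 0.31. SYNC, an intermediate filament protein, fell from 7.75 ± 4.77 to 0.405 ± 0.0199 (−2.52 ± 0.34). The readthrough genes INO80B-WBP1 (−2.35 ± 0.34) and ATP6V1G2-DDX39B (−1.41 ± 0.26) share their reads with the genes they join and are uncertain. HIF targets rose in 27 of 29 cases (29 adjusted over the list alone), with HILPDA at 3.32 and NDUFA4L2 at 2.55, and glycolysis genes in 17 of 18 (17 alone), with HK2 at 2.47. The list test gave adjusted p = 3.43e-42 and 1.17e-27, or adjusted p = 0.331 and 0.354 with an estimated correlation. ATF4 targets rose in 8 of 15 cases (11 alone), with STC2 at 1.94 and DDIT3 at 1.35, and sterol synthesis genes fell in 12 of 24 (13 fell and 3 rose alone), with INSIG1 at −0.90 and HMGCS1 at −0.76. In camera this gave adjusted p = 2.9e-11 and 1.07e-05, adjusted p = 0.331 for both with an estimated correlation. Fatty acid synthesis genes fell in 4 of 11 cases and rose in 1 (6 and 1 alone), the riser being the desaturase SCD at 0.43. From camera came adjusted p = 0.00179, or adjusted p = 0.337 with an estimated correlation. Ribosomal protein genes rose in 16 of 56 cases (28 alone), with RPS12 at 0.45, and G2/M genes in 6 of 26 (7 alone), with PTTG1 at 0.52, while mitochondrially encoded respiratory chain genes fell in 4 of 13 (5 alone), with MT-ND4L at −0.59. The median of the last list was −0.25, but −0.05 without μMeRe library 1, level with a normoxic library. At the preset correlation camera gave adjusted p = 1.16e-13, 0.000412 and 0.00836, or adjusted p = 0.523, 0.615 and 0.662 with an estimated correlation. Amino acid genes, S phase genes and the 4 measured ovary identity genes did not pass as lists (camera adjusted p = 0.426, 0.534 and 0.801). In all, 1502 of 14212 genes changed, 843 up and 659 down. The count was 923 without μMeRe library 2 and 789 without normoxic library 1.

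SKOV3, also an ovarian carcinoma line, showed HIF targets at higher levels as a group although no single gene passed in the main fit. The signal of CA9 was 21.7 ± 2.96 in the μMeRe device against 0.738 ± 0.617 in the normoxic device (SD, n = 2; log2 3.75 ± 0.36, limma adjusted p = 0.15). ADM was at 92.1 ± 13.1 against 23.9 ± 1.10 (1.89 ± 0.24), EGLN3, an oxygen-sensing prolyl hydroxylase, at 25.9 ± 3.60 against 5.49 ± 0.0744 (2.04 ± 0.27) and NDRG1 at 1.87 ± 0.26 (limma adjusted p = 0.25 for each). Adjusted over the list alone, 18 of 31 HIF targets, 7 of 19 glycolysis genes and 6 of 11 secreted angiogenic factors rose, with list medians of 1.13, 0.80 and 0.90. The camera test gave adjusted p = 1.03e-40, 7.88e-18 and 2.92e-10, adjusted p = 0.331 for each with an estimated correlation. Lists of sterol synthesis (median −0.42) and fatty acid synthesis (median −0.28) lay lower and mitochondrially encoded respiratory chain genes (median 0.65) higher, each with 0 members passing over all genes or alone. Tested by camera, this gave adjusted p = 1.55e-07, 0.000121 and 3.27e-05, or adjusted p = 0.51, 0.331 and 0.506 with an estimated correlation. The libraries of the 2 devices overlapped in 2 of these lists: relative to the normoxic mean, sterol synthesis lay at −0.21 and −0.58 in the μMeRe libraries against −0.32 and 0.32 in the normoxic ones. Mitochondrially encoded genes lay at 0.39 and 0.94 against 0.60 and −0.60, so neither list separated the devices, and the normoxic libraries were split. In all, 0 of 14617 genes changed (limma; smallest adjusted p 0.0688, and 434 genes had an unadjusted p under 0.05, 357 of them higher). This call depended on the fit: 24 genes passed with a replicate block, 1055 with a crossed one and 253 with a spread shared over 32 libraries. The 2 normoxic libraries differed with an SD of 0.631 on the log2 scale, the widest of the 16 groups, and the count was 191 and 49 without normoxic libraries 1 and 2 and 28 and 21 without μMeRe libraries 1 and 2. In those fits, in that order, CA9 was at 4.12, 3.38, 3.88 and 3.61. Without normoxic libraries 1 and 2, ADM was at 1.94 and 1.85, EGLN3 at 2.05 and 2.03 and NDRG1 at 1.94 and 1.79. ADM was at 2.04 without μMeRe library 2, and EGLN3 at 2.18 without μMeRe library 1.

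**Figure D3:**
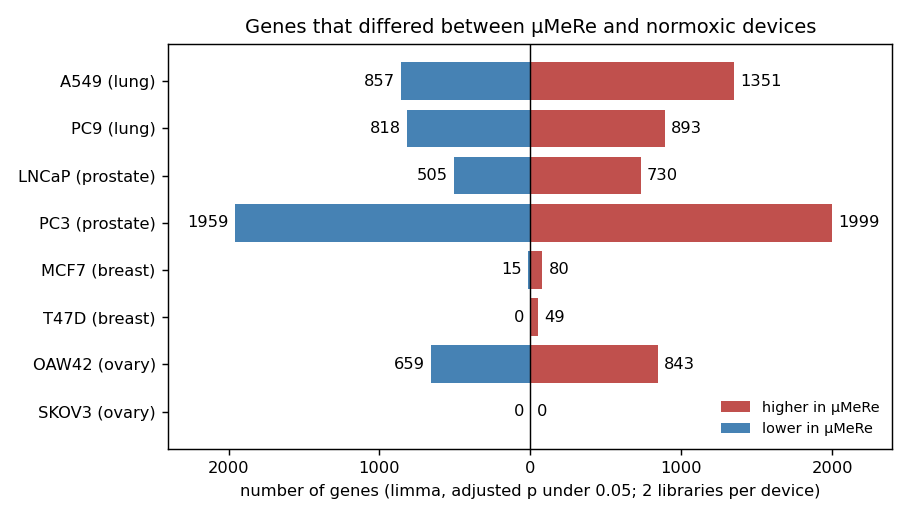
Number of genes (x axis) higher (red, right) or lower (blue, left) in the μMeRe device in each line (y axis), from limma on 2 libraries per device. Counts ran from 1999 higher and 1959 lower in PC3 to 0 and 0 in SKOV3, whose replicates differed most.

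Of the genes tested in all 8 lines, 223 rose in at least 4 lines, 44 in at least 6 and 19 in at least 7, while 65 fell in at least 4 and 0 in at least 6 (limma calls per line). Falls could reach 6 lines at most, as T47D and SKOV3 had none, so these counts do not compare rises with falls. If the lines' calls were independent, 2.53 and 1.08 genes would have risen or fallen in at least 4 lines. In 282 genes the direction differed, with a rise in at least 1 line and a fall in at least 1 other.

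Genes that responded differently among the lines were sought next. PLOD2 varied most, with an SD of 1.58 over the 8 log2 fold changes, from −0.20 in T47D to 4.94 in LNCaP (limma F-test adjusted p = 2.5e-09). GDF15 (chromosome 19, 18374731 to 18389176, plus strand) ranged from −0.66 in PC9 to 3.70 in LNCaP (SD 1.55, adjusted p = 0.0022), and HMOX1 (chromosome 22, 35380361 to 35394214, plus strand) from −0.21 in A549 to 3.50 in LNCaP (SD 1.18, adjusted p = 0.00051). CDKN1C, a cyclin-dependent kinase inhibitor, ranged from −0.49 in MCF7 to 3.38 in LNCaP (SD 1.29, adjusted p = 6.2e-07), and ANGPTL4 from 1.36 in LNCaP to 4.53 in PC3 (SD 1.16, adjusted p = 0.0056). The readthrough gene INO80B-WBP1 ranged from −2.35 in OAW42 to 1.93 in A549 (SD 1.54, adjusted p = 0.0053). These 6 genes passed without any 1 of the 32 libraries. In all, 471 of 10963 genes differed among the lines (83 with a replicate block), and 2149 had an unadjusted p under 0.05. The count was 767 without MCF7 normoxic library 1, 1288 without T47D μMeRe library 1, 253 and 289 without T47D normoxic libraries 1 and 2, and 1438 and 965 without SKOV3 normoxic libraries 1 and 2.

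Lines of 1 organ were then compared. Except in breast, 1 line was kept in DMEM and 1 in RPMI, confounding line and medium. Sterol synthesis, S phase and G2/M genes responded lower in A549 than in PC9 (median differences −0.53, −0.61 and −0.42). The list test gave adjusted p = 7.5e-14, 2.2e-11 and 7.5e-10, or adjusted p = 0.139, 0.331 and 0.268 with an estimated correlation. ASNS, at a signal of 58.4 ± 9.21 against 57.8 ± 5.97 in A549 and 18.8 ± 3.81 against 81.0 ± 2.26 in PC9 (SD, n = 2), responded more positively in A549 by 2.07 ± 0.43 (SE, limma adjusted p = 0.034), as did TP53INP1 by 1.83 ± 0.29. SLCO4A1, an organic anion transporter, responded more positively in PC9, with a difference of −1.96 ± 0.31, as did OLFML2A at −1.67 ± 0.36. The fold changes differed in 29 genes, 18 higher in A549 and 11 in PC9, or 10 and 11 after median-of-ratios rescaling, when ASNS at 2.02 no longer passed. With any 1 of the 8 libraries left out, ASNS (1.88 to 2.27) and OLFML2A (−1.79 to −1.55) did not pass, and OLFML2A did not with a pseudocount of 0.1 (−1.68). TP53INP1 did not pass without A549 μMeRe library 1 (1.79), A549 normoxic library 2 (1.63) or PC9 normoxic library 1 (1.90) or 2 (1.76), nor SLCO4A1 without A549 normoxic library 1 (−1.73) or PC9 normoxic library 1 (−1.97) or 2 (−1.94). With a replicate block SLCO4A1 alone passed. The G2/M difference was −0.27 without A549 μMeRe library 1. The count was 1, 8, 1 and 1 without A549 μMeRe libraries 1 and 2 and normoxic libraries 1 and 2, and 11, 5, 0 and 0 without those of PC9, with 833 genes at an unadjusted p under 0.05 in the full limma fit.

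Between the prostate lines, fatty acid synthesis had medians of 0.32 in LNCaP and −0.48 in PC3 over the genes tested in all lines. The difference of 0.78 passed camera at adjusted p = 1.2e-12 and, unlike each line's list, with an estimated correlation (adjusted p = 0.0107). ATF4 targets had medians of 0.66 in LNCaP and 0.01 in PC3. The median per-gene difference was 1.14 (camera adjusted p = 4.7e-06, or adjusted p = 0.193 with an estimated correlation). PLOD2 went from 81.1 ± 2.96 to 138 ± 4.87 in PC3 (SD, n = 2), so that its response was larger in LNCaP by 4.19 ± 0.29 (SE, limma adjusted p = 4.7e-09), and that of HMOX1 by 3.47 ± 0.48 (adjusted p = 0.00019). ANGPTL4 responded more in PC3, with a difference of −3.17 ± 0.59, and the calcium channel ITPR1 with −1.95 ± 0.43, and neither passed with a pseudocount of 0.1 (−1.99 and −1.94). PLOD2 and HMOX1 passed with any 1 of the 8 libraries left out, ITPR1 in none of those fits (−2.12 to −1.77), and ANGPTL4 not without LNCaP μMeRe library 2 (−3.09), LNCaP normoxic library 2 (−3.11) or PC3 μMeRe library 2 (−3.01). Under a replicate block 26 genes differed, without ITPR1. In the main fit the fold changes differed in 77 genes, 54 higher in LNCaP and 23 in PC3. The count was 64, 28, 28 and 24 without LNCaP μMeRe libraries 1 and 2 and normoxic libraries 1 and 2, and 36, 27, 29 and 27 without those of PC3.

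Between the breast lines, S phase genes set the responses apart, with medians of 0.05 in MCF7 and −1.53 in T47D (difference 1.58, or 0.98 without T47D μMeRe library 2, camera adjusted p = 2.7e-30, or adjusted p = 0.0857 with an estimated correlation). ATAD5, which unloads the sliding clamp after replication, responded more positively in MCF7 by 2.25 ± 0.53 (SE, limma adjusted p = 0.023) and E2F1 (chromosome 20, 33675477 to 33686385, minus strand) by 2.23 ± 0.45. CDKN1C (chromosome 11, 2883213 to 2885775, minus strand) went from a signal of 2.35 ± 0.631 to 14.4 ± 6.88 in T47D and from 6.75 ± 0.949 to 4.56 ± 0.973 in MCF7 (SD, n = 2), a difference of −2.62 ± 0.33 (adjusted p = 0.00018), and MT1X had a difference of −2.62 ± 0.67. CDKN1C passed with any 1 of the 8 libraries left out. E2F1 did not pass without T47D μMeRe library 2 (1.42) or normoxic library 1 (2.25). ATAD5 did not pass without MCF7 μMeRe library 2 (2.09), MCF7 normoxic library 2 (1.94), T47D μMeRe library 2 (1.95) or T47D normoxic libraries 1 (2.36) and 2 (2.14), nor MT1X without MCF7 μMeRe library 1 (−1.95), MCF7 normoxic libraries 1 (−2.44) and 2 (−2.80), T47D μMeRe library 2 (−2.12) or T47D normoxic libraries 1 (−2.55) and 2 (−2.68). With a replicate block 53 genes differed, without ATAD5, E2F1 and MT1X. In the main fit the fold changes differed in 267 genes, 162 of them higher in MCF7. The count was 190, 119, 388 and 141 without MCF7 μMeRe libraries 1 and 2 and normoxic libraries 1 and 2, and 869, 61, 50 and 89 without those of T47D.

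Between the ovarian lines, the secreted protein NXPH4 and the cytokine TGFB1 responded more positively in OAW42, by 2.24 ± 0.40 and 1.99 ± 0.39 (SE, limma adjusted p = 0.013 and 0.031). NOTCH3 (chromosome 19, 15159038 to 15200995, minus strand), a receptor of cell-to-cell signalling, and the secretory kinase FAM20C responded more positively in SKOV3, with differences of −1.86 ± 0.29 and −1.84 ± 0.30 (adjusted p = 0.0037 and 0.0078). With a replicate block 0 genes differed, so none of these 4 passed. In the main fit NOTCH3 passed with any 1 of the 8 libraries left out. FAM20C did not pass without OAW42 μMeRe library 2 (−1.72) or normoxic library 1 (−1.80), NXPH4 without those (2.10 and 1.87) or SKOV3 μMeRe library 1 (2.08), and TGFB1 without those 3 (1.36, 1.80 and 1.73) or OAW42 normoxic library 2 (2.17). The fold changes differed in 13 genes, 5 higher in OAW42 and 8 in SKOV3, with 555 at an unadjusted p under 0.05. The count was 4, 3 and 6 without OAW42 μMeRe library 2 and normoxic libraries 1 and 2, and 293 without SKOV3 normoxic library 1.

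**Figure D4:**
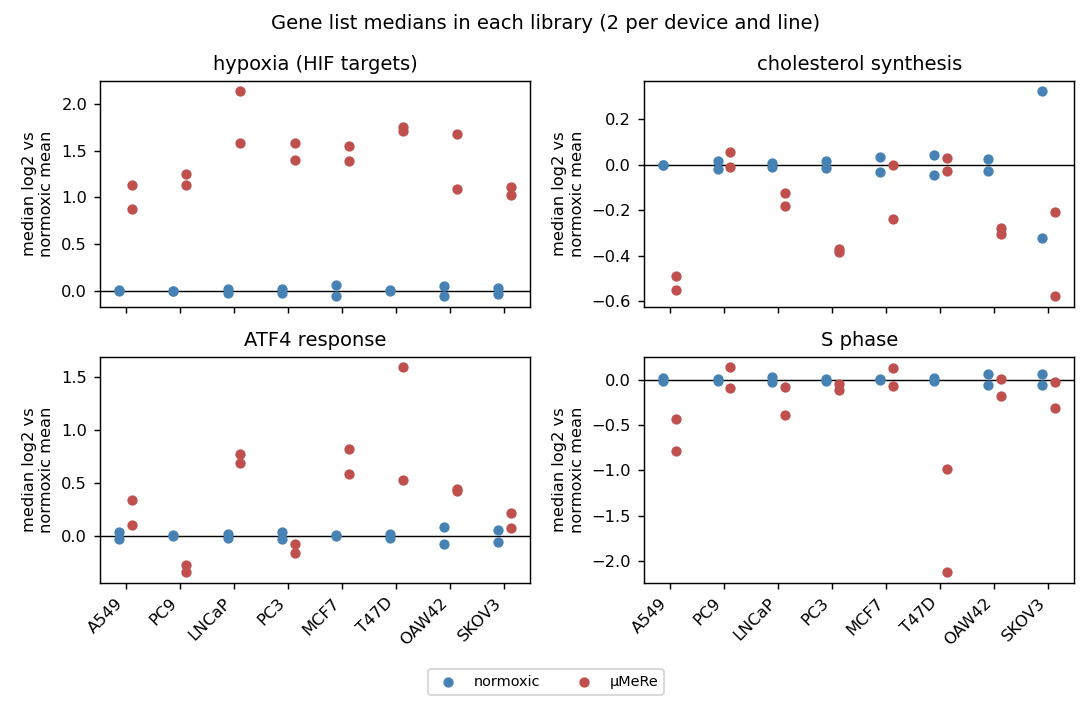
Median log2 signal of 4 gene lists (panels: hypoxia, cholesterol synthesis, ATF4 response, S phase) relative to the normoxic mean (y axis) in each line (x axis), with 1 point per library, 2 μMeRe (red) and 2 normoxic (blue). In the hypoxia panel μMeRe libraries lay between 0.88 and 2.13 in every line, and in the S phase panel T47D μMeRe library 2 lay far below the others at −2.13.

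On average, responses were slightly more alike within an organ than between organs. Fold changes correlated across genes at a mean r of 0.410 between lines of 1 organ and 0.334 between others. The difference was 0.0768 (exact two-sided permutation test, p = 0.0190). Only LNCaP, MCF7 and SKOV3 were closest to the other line of their organ. The closest pair was PC3 and OAW42 (r = 0.4965). Genes are not independent replicates. Leaving out 1 line kept the difference between 0.0493 and 0.106, but the permutation test did not pass without LNCaP (p = 0.171), PC3 (p = 0.162), MCF7 (p = 0.229), OAW42 (p = 0.0762) or SKOV3 (p = 0.152), nor with a length and GC trend removed (0.0448, p = 0.0762).

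Across the 8 lines, a stronger hypoxia response tended to come with a stronger glycolysis response, but none of 7 relations passed adjustment in the main setting. Without shared members, the median of the glycolysis list had Pearson's r of 0.79 with that of the hypoxia list (exact permutation p = 0.00992, adjusted p = 0.0694) and Spearman's rho of 0.74 (exact permutation p = 0.0458, adjusted p = 0.268). It fell to r = 0.41 without LNCaP and T47D, the lines farthest from the median hypoxia response, so in the main setting it depended on them. It passed at r = 0.89 with a transcript length and GC trend removed (exact permutation, adjusted p = 0.00694; r = 0.82 without LNCaP and T47D) and at r = 0.88 without MCF7 (exact permutation, adjusted p = 0.00972; r = 0.98 without LNCaP and T47D as well). ATF4 targets had r = 0.66 and rho = 0.64 (exact permutation p = 0.0804 and 0.0962), and ribosome biogenesis r = −0.65 (exact permutation p = 0.0871), or r = 0.30 and −0.02 without those lines. Respiratory chain, sterol synthesis, S phase and G2/M lists had r = −0.25, 0.50, −0.41 and 0.40.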

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

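In this part, the tests of an exchanged label in SKOV3, of 1 μMeRe library alone in T47D and of the culture medium for the ATF4 targets were chosen after the result was seen, as were the removal of a transcript length and GC trend and the estimated correlation.

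Some lines stood apart from the other 7 in a gap test on the 8 fold changes, in 10 of 58 sets tested. The 2.9 expected by chance (1 in 20) holds for independent sets, but these overlap and most genes were picked by size. It decides nothing here. LNCaP was highest for the medians of glycolysis (1.64), fatty acid synthesis (0.32) and collagen genes (1.55) and for PFKFB4 (3.80). T47D was lowest for the S phase median (−1.53), ESCO2 (−2.0) and CDC25A (−1.80), and highest for immediate early genes (1.07) and NDRG1 (5.73). PC3 was lowest for SLC2A6 (−1.0). List medians here cover genes tested in all 8 lines. Over all members in LNCaP, the collagen median was 1.34, or 0.67 without the 2 hypoxia members.

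Single genes also differed between lines. Among 8 lines, the F-test singled out PLOD2 (SD of the fold changes 1.58), GDF15 (1.55), INO80B-WBP1 (1.54), CDKN1C (1.29), HMOX1 (1.18) and ANGPTL4 (1.16). Between A549 and PC9 the response differed for ASNS (2.07), TP53INP1 (1.83), SLCO4A1 (−1.96) and OLFML2A (−1.67), and between LNCaP and PC3 for PLOD2 (4.19), HMOX1 (3.47), ANGPTL4 (−3.17) and ITPR1 (−1.95). Between MCF7 and T47D it differed for ATAD5 (2.25), E2F1 (2.23), MT1X (−2.62) and CDKN1C (−2.62), and between OAW42 and SKOV3 for NXPH4 (2.24), TGFB1 (1.99), NOTCH3 (−1.86) and FAM20C (−1.84). With a replicate block these 4 did not pass, nor did ASNS, TP53INP1, OLFML2A, ITPR1, ATAD5, E2F1 and MT1X.

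Gene lists differed between the lines of an organ in 45 of 128 camera tests at the preset correlation, and 1, fatty acid synthesis in prostate, also passed with an estimated correlation (adjusted p = 0.0107); the smallest adjusted p with an estimated correlation was 0.0857 in lung, 0.0857 in breast and 0.268 in ovary. As medians of the differences per gene in log2 response, A549 minus PC9 was −0.13 for the TCA cycle, −0.17 for nuclear and 0.51 for mitochondrially encoded respiratory chain genes, −0.53 for sterol synthesis, 0.21 for amino acid genes, 0.33 for ATF4 targets, −0.12 for endoplasmic reticulum chaperones, −0.61 for S phase, −0.42 for G2/M and 0.75 for histones. LNCaP minus PC3 was 0.51 for HIF targets, 0.47 for glycolysis, −0.22 for nuclear and 0.48 for mitochondrially encoded respiratory chain genes, 0.19 for sterol synthesis, 0.78 for fatty acid synthesis, 0.46 for amino acid genes, 1.14 for ATF4 targets, −0.28 for heat shock, 0.47 for NRF2 targets, −0.28 for G2/M, −0.21 for ribosomal proteins, −0.34 for ribosome biogenesis, 0.23 for p53 targets and 0.90 for collagen genes. MCF7 minus T47D was −0.36 for HIF targets, −0.25 for glycolysis, −0.25 for sterol synthesis, 0.51 for serine metabolism, 0.18 for heat shock, 1.58 for S phase, −0.16 for ribosomal proteins, 0.38 for ribosome biogenesis, −0.33 for p53 targets, −0.95 for angiogenic factors, −0.29 for autophagy and −1.03 for histones. OAW42 minus SKOV3 was 0.27 for HIF targets, 0.24 for glycolysis, 0.14 for nuclear and −0.82 for mitochondrially encoded respiratory chain genes, 0.25 for ATF4 targets, 0.15 for G2/M, 0.34 for p53 targets and 0.61 for histones.

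Leaving out 1 library moved 28 of these 45 by over 1.5 times, 3 of them across 0. In lung the ranges were −0.13 to −0.08 for the TCA cycle, 0.12 to 0.36 for amino acid genes, 0.29 to 0.52 for ATF4 targets, −0.25 to −0.05 for endoplasmic reticulum chaperones and −0.52 to −0.27 for G2/M. In prostate they were 0.28 to 0.71 for HIF targets, −0.39 to −0.06 for nuclear and 0.29 to 0.67 for mitochondrially encoded respiratory chain genes, and 0.30 to 0.47 for amino acid genes. Heat shock ran from −0.39 to −0.16, ribosomal proteins from −0.38 to −0.04, ribosome biogenesis from −0.49 to −0.19 and p53 targets from 0.18 to 0.39. In breast they were −0.42 to −0.07 for glycolysis, −0.34 to −0.13 for sterol synthesis, 0.17 to 0.71 for serine metabolism and 0.14 to 0.45 for heat shock. S phase ran from 0.98 to 2.08, ribosomal proteins from −0.39 to 0.07 and p53 targets from −0.59 to −0.08. In ovary all 8 moved: 0.09 to 0.42 for HIF targets, −0.02 to 0.52 for glycolysis, −0.23 to 0.51 for nuclear and −1.46 to −0.32 for mitochondrially encoded respiratory chain genes. ATF4 targets ran from 0.17 to 0.31, G2/M from 0.07 to 0.25, p53 targets from 0.11 to 0.36 and histones from 0.22 to 0.94.

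Chance is argued against for the common response as a whole, as far as 100 of 128 possible assignments can tell. When the devices were exchanged within lines at random, 1 of the 100, the real one, gave as many as 1938 changed genes. The highest of the others gave 787.

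The SKOV3 libraries disagreed within each device, and along opposite directions, with a correlation of −0.67 across genes between the replicate differences of the devices. A smooth trend on transcript length and GC took up 24.8% of the variance of that axis (27.8% in LNCaP and 24.3% in MCF7). Removing the trend left a correlation of −0.601, which argues against it as the whole cause. The rule that over 80% be left was set after these values were seen, so a partial effect stays open. An exchanged label is argued against by the hypoxia list, in which the lowest μMeRe library lay 0.994 above the highest normoxic one. RNA of another line in 1 pair is argued against by genes far higher in another line. Their largest absolute median along the axis was 0.177 (84 genes of PC3). A narrower first choice left at most 1 gene per line and was widened before its result was seen. What set the pairs apart stays open, and no biological explanation was tested.

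In T47D the S phase genes lay far lower in the μMeRe device (median −1.57), while the μMeRe replicates disagreed. Neither the length and GC trend nor 1 library accounts for it. The median was −1.55 without the trend and −0.98 and −2.13 without μMeRe libraries 2 and 1. An effect of oxygen limitation may underlie it. The difference from MCF7 passed at the preset correlation (adjusted p = 2.7e-30) and missed with an estimated one (adjusted p = 0.0857). A bound of 0.05 on the latter p had been set as evidence against it. A missed threshold shows no equality, so the effect stays open. S phase genes fell in A549 too (μMeRe libraries −0.78 and −0.44), so T47D was not alone. A difference in density or growth between the devices was not tested.

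ATF4 targets ran from −0.38 in PC9 to 1.05 in T47D, which was at 0.52 without μMeRe library 2 and so below LNCaP and MCF7. A trend on length and GC is argued against, since the range over lines kept 100.5% of its width after the trend was removed (1.30 before and 1.31 after). Culture medium as the whole cause is argued against by PC9 and LNCaP, both maintained in RPMI, at −0.31 and 0.66 over the 14 members tested in all 8 lines, while the test itself decides little: over the 14 members the RPMI lines averaged 0.254 and the DMEM lines 0.419 (exact permutation p = 0.607 over 56 splits, smallest possible p 0.0179). A stronger hypoxia response may bring a stronger ATF4 response, with Pearson's r of 0.656 across 8 lines (exact permutation p = 0.0804, and r = 0.30 without LNCaP and T47D), which leaves it open. Differences between the cancer types themselves stay open too, untested.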

How the results depend on the processing

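The settings added after the data were seen are listed with the data processing. No count-based test was run.

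Among the gene values named or listed, 1322 of 1343 kept their direction and side of the threshold with a pseudocount of 0.1, 1317 of 1327 without the filter, 1308 of 1343 after rescaling and 1232 of 1343 with the trend removed. With 1 library or line left out, 4979 of 6008 kept both, 503 lost the call and 1 reversed: HIF1A in T47D, which had not passed, was at 0.42 and −0.33 without T47D μMeRe replicates 1 and 2. Of 312 list results, 309 kept theirs with the other pseudocount, 310 without the filter, 305 after rescaling, 287 with the trend removed and 295 without hypoxia members. ATF4 targets in A549 and SKOV3 and androgen receptor targets in LNCaP lost their call both with the trend removed and without hypoxia members. S phase genes in LNCaP and nuclear respiratory chain genes in SKOV3 did too, but these lists hold no hypoxia members, so the second loss came from adjusting p again over changed lists. With an estimated correlation, 0 of 280 lists within lines passed in place of 152 (camera, lowest adjusted p 0.331, lowest unadjusted p 0.00408) and 3 of 32 common lists in place of 18. Where a result changed, the cause was not tested, except that fewer lines or libraries give fewer degrees of freedom.

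With a spread shared over 32 libraries the changed genes were 373 in A549, 245 in PC9, 852 in LNCaP, 612 in PC3, 197 in MCF7, 1672 in T47D, 191 in OAW42 and 253 in SKOV3, since each line then takes on the spread of the noisier lines or gives up its own. With the trend removed they were 2678 in LNCaP (1271 up and 1407 down) and 3 in SKOV3, the lines differed in 1079 genes, and the organ contrasts in 54 (lung), 122 (prostate) and 545 (breast). Organ similarity was then 0.0448 and did not pass, and 1 relation did. The common response counted 3151 genes with libraries as replicates, 334 in the DMEM lines, 51 in the RPMI lines and 963 without SKOV3 and T47D.

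Replicate numbers pair nothing that the labels name, and the replicate differences of the devices correlated at 0.04, −0.03, −0.15, 0.02, 0.09, −0.06, 0.01 and −0.67 in A549, PC9, LNCaP, PC3, MCF7, T47D, OAW42 and SKOV3. With a replicate block the counts were 178 in MCF7, 596 in T47D, 2407 in OAW42 and 24 in SKOV3, 83 among lines, and 1, 26, 53 and 0 in lung, prostate, breast and ovary (limma, 350 genes at an unadjusted p under 0.05 in ovary), and no other count moved by over 1.5 times. A crossed pairing gave 2803 genes in LNCaP and 1055 in SKOV3.

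Leaving out 1 library moved the counts within 1013 to 3261 in A549, 753 to 3387 in PC9, 380 to 4101 in LNCaP, 2358 to 4442 in PC3, 35 to 159 in MCF7, 9 to 6086 in T47D, 789 to 1969 in OAW42 and 21 to 191 in SKOV3, 253 to 1438 among lines, and 0 to 11, 24 to 64, 50 to 869 and 3 to 293 in the lung, prostate, breast and ovary contrasts. The lone library left in a device was assumed to vary like the others. Of the list medians that passed, 55 of 152 within lines moved by over 1.5 times in some leave-out, 7 of them across 0, and so did 28 of 45 organ differences, 3 of them across 0. Most were in SKOV3 (13 of 16), MCF7 (10 of 18) and T47D (9 of 19). Leaving out 1 line moved the common count within 1223 to 2211, organ similarity within 0.0493 to 0.106, the relations passed within 0 to 1 and the common lists within 16 to 19.

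Depth may limit low genes, as the lowest values (0.0350 to 0.0739) may stand for 1 read. Replicate spread limits SKOV3, MCF7 and T47D: the median SD within a device was 0.290, 0.226 and 0.183 against 0.113 in PC3.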

Other observations

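The gene groups in this part were picked for description after their values were seen, from lists fixed earlier, and the estimated correlation was added after the data were seen.

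Genes of glycogen handling, among them the synthase GYS1 (common log2 change 0.75 ± 0.08, SE, n = 8 lines), the branching enzyme GBE1 and the phosphorylase PYGL, were higher as a list in 8 of 8 lines at the preset correlation. Of 10 or 11 members measured, 7 rose in A549, 6 in PC9, 5 in LNCaP (1 fell), 7 in PC3 (2 fell), 4 in MCF7, 0 in T47D, 2 in OAW42 (2 fell) and 0 in SKOV3. The medians were 0.48 in A549, 0.44 in PC9, 0.83 in LNCaP, 0.75 in PC3, 0.32 in MCF7, 0.35 in T47D, 0.20 in OAW42 and 0.50 in SKOV3, with camera adjusted p of at most 0.0499 and adjusted p = 0.331 to 0.428 with an estimated correlation. With 1 normoxic library left out, the median was 0.18 in MCF7 (library 2), 0.08 in T47D (library 2) and 0.31 in SKOV3 (library 1). The calls of T47D and OAW42 lay close to the threshold: this list shares no member with the hypoxia list, yet they did not pass once p was adjusted again with shared members left out of other lists.

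Metallothionein genes were higher as a list in each of the 7 lines in which at least 3 were measured. The medians were 0.67 in A549, 1.19 in PC9, 2.66 in LNCaP, 0.88 in PC3, 0.54 in MCF7, 1.32 in T47D and 0.61 in OAW42 (camera adjusted p of at most 0.0419, and adjusted p = 0.331 to 0.592 with an estimated correlation). The median was 0.44 in A549 without μMeRe library 1 and 0.28 in MCF7 without μMeRe library 2. The list of OAW42 did not pass after rescaling or with the length and GC trend removed.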
